A study of Rattus norvegicus with 8 samples.

How the data were processed

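Total RNA from rat kidney was labelled with Cy3 (0.1 µg per array) and hybridised to Agilent rat miRNA arrays after TRIzol extraction and a mirVana kit, per the labels' protocols. The deposited per-array files are scanner output: spot intensity values on a linear scale, background-corrected but not normalized between arrays, made with Agilent Feature Extraction, per the file headers version 10.7.3.1 and per the submitters' processing notes version 9.5.3. The deposited table of all arrays holds log2 values of the gene-level signal; set against each array's own gene-level signal over detected miRNAs, it correlated at 0.985 to 0.999, and its 699 features include 22 controls. Its column medians ran from -3.32 to -3.15, its direction and log2 scale follow from that comparison, and the reason for its centring is not given in the sources used here. It served only as an alternative.

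Each array held 14255 spots, of which 13540 measured 677 rat miRNAs through 1644 probes. Control spots and spots marked as outliers (3.34% to 7.66% of spots per array) were left out; 0 spots were saturated. A probe's value was the mean background-corrected signal over its spots. Between 279 and 331 probes were detected per array, a probe being detected when over 0.5 of its spots were well above background. Values were divided by the array's 75th percentile over the 248 probes detected on all arrays (407 to 656 intensity units), floored at -5.41 on the log2 scale and log2-transformed. The floor understates the change of dim miRNAs. It also gives all arrays below it the same value, which understates their spread, so p-values of miRNAs at the floor can be too low. A miRNA was represented by its brightest probe (summing its probes gave 27, 37 and 71 calls for the 3 comparisons, against 29, 51 and 76) and tested when detected on at least 2 arrays. Where a miRNA was not well above background on any array of a group, only a bound is given, as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the miRNA's own floored value. Names are those of the array's design. No pair of arrays held identical values.

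Groups came from the titles. limma 3.58.1 in R 4.3.3 fitted 3 group means to all 8 arrays with a moderated variance that follows intensity, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over the 194 miRNAs. Of the called miRNAs whose arrays did not overlap, the 12 with the greatest rise and the 12 with the greatest fall per comparison were named, and members of the fixed lists could be named besides. Of 19 lists, 11 had 3 or more tested members and were tested with camera at an inter-miRNA correlation of 0.01, with an estimated correlation and fry as alternatives. None of the 3 lists called by camera passed with an estimated correlation, and all 3 passed by fry, as did the miR-30 and leukocyte lists in the same comparison. Of the 11 lists, fry passed 8 for MSC against untreated and 0 for MSC against PBS, where camera passed 0. fry tests whether a list's members move 1 way without comparing them with other miRNAs. Reversal and agreement were set beside 1000 simulated data sets with the residual spread per miRNA. On 50 simulated data sets of 194 miRNAs for the PBS against untreated comparison, 82.0% of miRNAs changed 2-fold and 98.0% of those changed 4-fold were recovered, with 3.83% false calls. A reversal slope set to -0.5 came back as -0.50 over the changed miRNAs alone. These sets had independent noise per miRNA and no floor, row effect or outlying array. They check the procedure, and their rates need not hold for the real arrays.

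All 8 arrays were on 1 slide and had 1 scan time, so neither could act as a batch. They lay in 2 rows of the slide: row 1 held the untreated arrays and PBS replicates 2 and 3, row 2 held PBS replicate 1 and the MSC arrays. The replicate numbers were checked as pairs. Between the PBS and MSC groups the deviations of same-numbered arrays from their group means correlated across miRNAs at 0.11, 0.53 and 0.39. All were above 0.1, so the numbers were treated as a possible pairing of these arrays. The highest correlations with an array of another number were 0.10, -0.41 and 0.25, so the first pair hardly stood out. Deviations from a mean of 3 arrays cancel out, so the 3 values are not independent. The pairing is therefore uncertain, and the main fits left it out. Between untreated and PBS the 2 correlations were 0.18 and -0.24, and between untreated and MSC they were -0.06 and -0.07, so no pairing was taken there. The replicate block, an alternative, used the numbers of all groups, the untreated arrays included. Neighbouring miRNAs were found by name in a table of the GRCr8 assembly (192 of 194 miRNAs matched, neighbours within 10000 bases), used for neighbour relations only. Alternatives were the percentile over all probes, no scaling, quantile and spike-in scaling, normexp, the deposited gene-level signal and table, the sum of probes, other detection filters, no intensity trend, only the compared groups, the replicate and row blocks, and each array left out. The per-array files used here hold no column of mean spot signal, so normexp, with an offset of 50, used the median spot signal, without spots whose local background exceeded 2 times the array's median. The scalings by percentile and quantile, the no-scaling setting, the filters, blocks and left-out arrays were chosen before the data were examined; normexp in this form, spike-in scaling, the fits within a row, the count of calls kept under 5 scalings, the correlated and paired noise and the fit without 2 MSC arrays were chosen after seeing the data.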

Results

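MicroRNAs (miRNAs), the short RNAs that repress messenger RNAs, were measured with 8 one-colour arrays in kidneys of male Sprague-Dawley rats. The groups were untreated rats (n = 2), rats given 6 mg/kg of cisplatin, a platinum drug that injures the kidney, followed 24 h later by phosphate-buffered saline (PBS, n = 3), and rats given cisplatin followed 24 h later by the cells that the labels call MSCs (n = 3). Kidneys were collected at day 5, 4 days after PBS or cells. The series' design text calls the replicates independent experiments; the labels do not say which arrays came from separate animals, so p-values measure the spread between these samples. Between 161 and 186 of the 677 rat miRNAs on the array were detected per array, and 194 miRNAs were tested. Across the tested miRNAs the arrays correlated at 0.992 to 0.995 within the PBS group and at 0.993 between the untreated arrays. Within the MSC group the correlations were 0.95 to 0.996, and between MSC and PBS arrays 0.957 to 0.976. MSC replicates 1 and 3 correlated at 0.996 with each other, and at 0.95 and 0.957 with MSC replicate 2. MSC replicate 2 correlated at 0.96 to 0.961 with the PBS arrays. By this measure it was slightly closer to the PBS arrays than to the other MSC arrays. The number of arrays limits the precision of every comparison.

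The first comparison asked which miRNAs differed in cisplatin-injured kidneys without cell treatment. In the PBS group, miR-34a, a transcriptional target of p53, rose 10.04-fold over untreated kidneys (log2 change 3.33 ± 0.50 SE, adjusted p = 0.0053), and its relatives miR-34c and miR-34b rose 3.54-fold and 3.02-fold. miR-146b, which is induced in inflammatory signalling, rose 8.50-fold (log2 change 3.09 ± 0.18 SE, adjusted p = 2.2e-05). miR-21, often raised in injured tissue, rose 4.85-fold (log2 change 2.28 ± 0.22 SE, adjusted p = 0.00046). miR-499 fell 4.94-fold, and miR-375 was at least 3.30-fold lower, since it was not well above background on any cisplatin array (adjusted p = 2.2e-05). All cisplatin arrays held the floor value for miR-375. Its p-value by limma thus rests on the spread of the untreated arrays and on the moderated variance. In all, 29 of 194 miRNAs passed an adjusted p of 0.05 by limma, 17 higher and 12 lower.

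Of the lists fixed in advance, 3 passed camera, a test of a list against the other miRNAs. Of 13 miRNAs that earlier rodent studies reported as raised by kidney injury, 7 rose, 0 fell and 6 did not pass (camera adjusted p = 1.95e-05; adjusted p = 0.057 with an estimated correlation); 7 rose and 1 fell when adjusted over the list alone. The risers were miR-34a, miR-146b, miR-21, miR-18a, miR-20a, miR-223 and miR-132, the last at least 1.51-fold higher. All 3 members of the miR-34 list rose, also when adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.28 with an estimated correlation). In the list of miR-17 and its related clusters, known from dividing cells, 3 of 11 members rose and 0 fell (camera adjusted p = 0.0080; adjusted p = 0.28 with an estimated correlation): miR-18a by 3.58-fold, miR-20a by 1.65-fold and miR-20b-5p by 1.56-fold. Adjusted over the list alone, 4 of the 11 rose and 1 fell. That list's camera adjusted p was 0.063 without untreated replicate 2. The 3 lists are not separate results, since miR-34a is also in the injury-raised list, as are miR-18a and miR-20a of the miR-17 list. The estimated correlation was 0.94 in the miR-34 list, 0.18 in the miR-17 list and 0.02 in the injury-raised list, against the preset 0.01.

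Other named miRNAs that rose were miR-1224 (2.85-fold), miR-31 (2.38-fold) and miR-1949 (1.75-fold), and at least 2.30-fold, 2.19-fold and 1.70-fold for miR-188, miR-21* and miR-222, none of which was well above background on an untreated array. The named miRNAs that fell less than miR-499 and miR-375 were miR-183, miR-362*, miR-342-3p, miR-126*, miR-186, miR-378, miR-30e, miR-26b, miR-378* and miR-27b, with log2 changes from -0.97 to -0.36. In the leukocyte list, miR-146b and miR-223 rose while miR-342-3p fell 1.94-fold, and the other 3 of 6 members did not pass (camera adjusted p = 0.64); adjusted over the list alone, 2 rose and 2 fell. The leukocyte list's median was -0.25 while its mean, 0.27, and the test pointed up. In the miR-200 list only miR-200c of 5 members passed, at least 1.44-fold higher (camera adjusted p = 0.30), and in the miR-30 list only miR-30e of 6 (camera adjusted p = 0.11), both also when adjusted over the list alone. No member of the stromal list (median 0.04, mean -0.01, camera adjusted p = 0.66), the miR-29 list or the let-7 list passed. In the tubule-enriched list only miR-30e of 12 members passed, falling 1.58-fold (camera adjusted p = 0.092, list median log2 change -0.37), also when adjusted over the list alone. miR-192 and miR-194, miRNAs abundant in kidney tubules, had log2 changes of -0.91 and -0.97 and did not pass (adjusted p = 0.62 and 0.54), although their PBS and untreated arrays did not overlap, because MSC replicate 2 widened the shared estimate of spread. Without that array their adjusted p was 0.0017 and 0.00052.

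Of the 194 tested miRNAs, 115 had non-overlapping values in the 2 groups, a separation that chance gives to 20% of miRNAs at these group sizes. Under 5 scalings of the arrays, 12 of the higher and 3 of the lower calls kept their direction and passed throughout: the higher ones include miR-34a, miR-34b, miR-34c, miR-146b, miR-21, miR-18a and miR-31, and the lower ones were miR-499, miR-375 and miR-126*. The split was 13 higher and 3 lower without scaling, and likewise 13 and 3 with spike-in scaling, against 17 and 12. With normexp background correction it was 5 and 9. There the log2 change of miR-146b shrank to 1.51, that of miR-499 to -1.13 and that of miR-375 to -0.58. miR-34c, miR-34b, miR-18a, miR-31 and miR-126* did not pass, at 0.81, 0.60, 0.63, 0.39 and -0.22. The normexp offset is added to every value, so it shrinks the changes of dim miRNAs by construction, in all 3 comparisons. The count was 2 without untreated replicate 1, 3 without untreated replicate 2, 15, 9 and 12 without PBS replicates 1, 2 and 3, and 66 without MSC replicate 2, since all arrays share 1 estimate of spread. It was 62 with only the 5 arrays of the compared groups. The arrays lay in 2 rows of 1 slide, and with the row as a block the count was 15, and 44 within row 1.

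**Figure D1:**
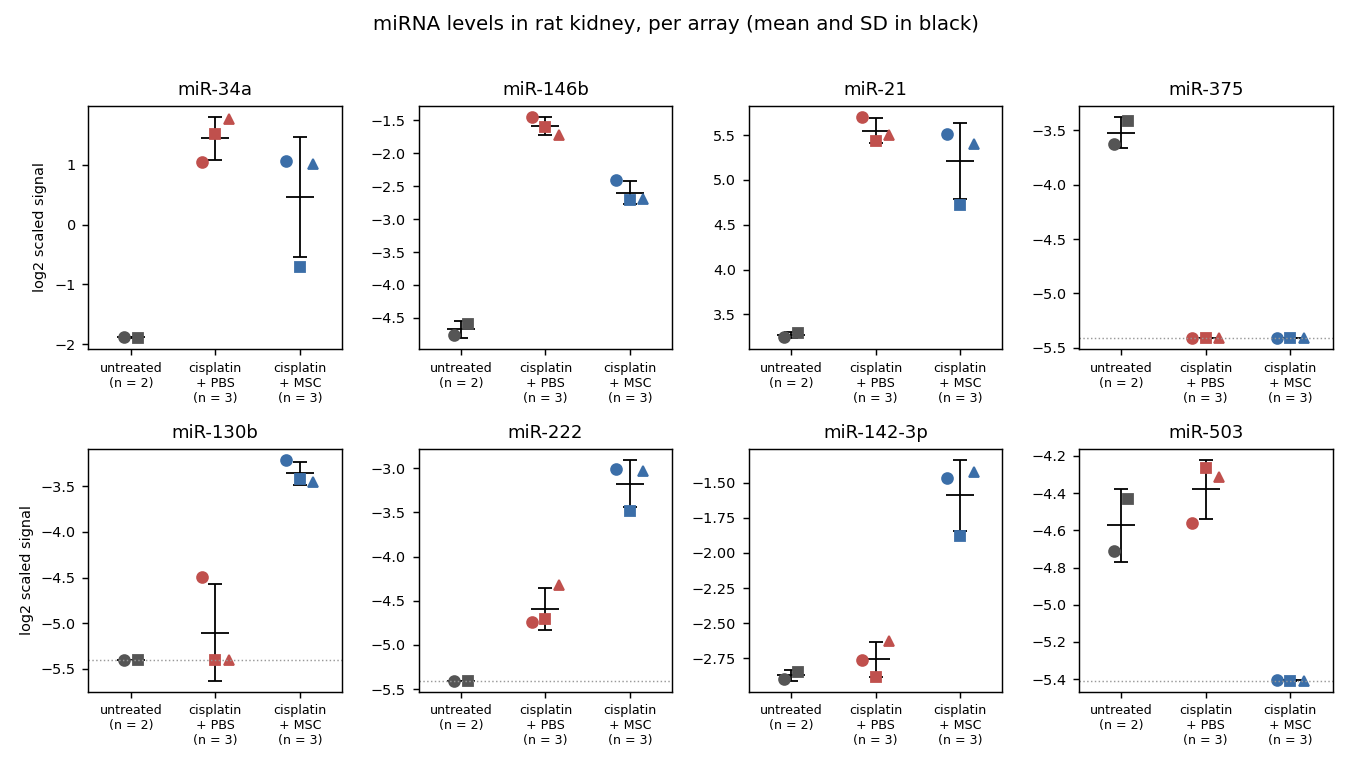
Level of 8 miRNAs on each array, as log2 of the background-corrected signal over the array's scaling value; circles, squares and triangles are replicates 1, 2 and 3, black bars are the group mean and SD, and the dotted line is the floor of -5.41. The top row shows miRNAs called between the PBS group and untreated kidneys, with miR-375 at the floor on all 6 cisplatin arrays, and the bottom row shows miRNAs called between the MSC and PBS groups.

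The comparison of cell treatment with PBS among cisplatin-treated rats asked what the cells changed. miR-130b rose 3.35-fold in the MSC group (log2 change 1.74 ± 0.25 SE, adjusted p = 0.0065). Its value was -4.49 on PBS replicate 1 and at the floor on PBS replicates 2 and 3, so this fold depends on the floor. miR-222, an inhibitor of the cell-cycle brake p27, rose 2.67-fold (log2 change 1.42 ± 0.19 SE, adjusted p = 0.0065). miR-142-3p, a miRNA of blood-forming cells, rose 2.25-fold (log2 change 1.17 ± 0.17 SE, adjusted p = 0.0065). miR-146b fell 2.02-fold from its PBS level (log2 change -1.01 ± 0.16 SE, adjusted p = 0.0083) and miR-503 fell 2.04-fold, to a level not detected on 2 of the 3 MSC arrays. miR-182 and miR-188 fell 1.73-fold and 1.80-fold. miR-132 fell 1.46-fold, but its log2 change was 0.08 with normexp background correction, where those of miR-188 and miR-503 were -0.0064 and -0.05 and did not pass. With normexp miR-130b, miR-222 and miR-146b passed at smaller log2 changes of 0.63, 0.63 and -0.60, and miR-182 did not pass. miR-188 lost its call in 15 of 23 other settings, miR-503 in 4 of 23 and miR-182 in 7 of 24. These 8 were the calls that kept their direction and passed under 5 scalings, out of 51 called in all, 38 higher and 13 lower.

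Among the other named miRNAs that rose were miR-210 (2.04-fold), which is induced by low oxygen, miR-199a-5p (1.83-fold), miR-221 (1.73-fold), which lies beside miR-222, miR-181a (1.71-fold) and miR-181d (1.65-fold). miR-7a, miR-532-5p, miR-196c and miR-125a-3p rose by log2 changes of 0.69 to 0.77. miR-96 and miR-183, which share a cluster with miR-182, fell 3.11-fold and 1.69-fold, and miR-322, which lies beside miR-503, fell 2.05-fold. miR-96 was detected on 1 of the 3 MSC arrays, so its fold is limited by the floor. miR-107, miR-103 and miR-148b-3p fell by 0.74, 0.73 and 0.63 on the log2 scale, and miR-542-5p was at least 1.46-fold lower.

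No list passed camera in this comparison. Of the let-7 list, let-7e, let-7b, let-7c and let-7i rose, by 1.48-fold, 1.39-fold, 1.33-fold and 1.30-fold, and 4 of 8 members did not pass (camera adjusted p = 0.10); 5 rose when adjusted over the list alone. The let-7 median change of 0.35 was 0.03 with quantile normalization, where let-7c turned to -0.06. In the miR-17 list, miR-25, miR-92a and miR-93 rose and the other 8 of 11 did not pass (camera adjusted p = 0.84). Of the stromal and smooth muscle list, miR-145 and miR-199a-5p rose and 5 of 7 did not pass (camera adjusted p = 0.74). In the injury-raised list, miR-146b and miR-132 fell, miR-199a-5p rose and 10 of 13 did not pass (camera adjusted p = 0.49). The injury-raised list's median was 0.17, while its mean, -0.12, and the test pointed down. The counts for these 3 lists were the same when adjusted over the list alone. In the leukocyte list miR-142-3p rose and miR-146b fell, also when adjusted over the list alone (camera adjusted p = 0.74), and in the miR-200 list miR-200b rose, with 3 rising when adjusted over the list alone (camera adjusted p = 0.34). No miR-30 or miR-34 member passed (camera adjusted p = 0.99 and 0.49), although 3 miR-30 members were higher and 2 lower when adjusted over the list alone (median 0.25, mean -0.25). In the tubule-enriched list, miR-10a-5p and miR-10b rose, likewise when adjusted over the list alone, and 10 of 12 did not pass (camera adjusted p = 0.99); the list's median was 0.14 and its mean -0.31. The medians of the injury-raised, stromal and miR-17 lists were above 0 here and below 0 with no scaling or spike-in scaling, those of the tubule-enriched and miR-30 lists were -0.02 without scaling, and that of the leukocyte list, -0.03, was 0.02 with quantile normalization.

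The direction of this comparison as a whole depended on the scaling. Over all tested miRNAs the median log2 change was 0.11, and it was -0.15 without scaling and -0.12 with spike-in scaling, so that modest rises are relative to the array's 75th percentile. The split of 38 higher and 13 lower became 5 and 9 with the percentile over all probes, 3 and 10 without scaling, and 3 and 8 with spike-in scaling. Non-overlapping groups were seen for 75 of the 194 tested miRNAs, where chance gives 10%. With the slide row as a block limma called 0 miRNAs (41 at an unadjusted p under 0.05), and within row 2, which held the 3 MSC arrays and PBS replicate 1, it called 0 (16 at an unadjusted p under 0.05). Both of these fits rest on PBS replicate 1 as the only PBS array in row 2. Most changes of the named miRNAs stayed about as large. Naming required that no PBS array, PBS replicate 1 included, overlapped an MSC array. That choice favours such a result, so it says little about an effect of the row. With the block the log2 change was 1.57 ± 0.27 SE for miR-222, 1.17 ± 0.26 SE for miR-142-3p and -1.15 ± 0.24 SE for miR-146b. For miR-130b it was 1.13 ± 0.18 SE, down from 1.74. PBS replicate 1 was also the only PBS array on which miR-130b lay above the floor. The count was 29 without untreated replicate 1, 17 and 11 without PBS replicates 1 and 2, 21 and 7 without MSC replicates 1 and 3, and 115 without MSC replicate 2. It was 29 with only the 6 arrays compared and 23 with normexp.

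The comparison of MSC-treated with untreated kidneys asked how far these kidneys still differed. miR-34a was 5.08-fold above untreated (log2 change 2.35 ± 0.50 SE, adjusted p = 0.0081), miR-146b 4.21-fold (log2 change 2.07 ± 0.18 SE, adjusted p = 0.00031), miR-18a 4.12-fold and miR-21 3.85-fold. miR-222 and miR-130b were at least 4.53-fold and 3.99-fold higher. miR-30c, a tubule-enriched member of the miR-30 family, fell 8.38-fold (log2 change -3.07 ± 0.69 SE, adjusted p = 0.0096), miR-96 fell 7.43-fold, miR-499 fell 5.70-fold and miR-30b-5p fell 4.63-fold. miR-96 was detected on 1 and miR-499 on 2 of the 3 MSC arrays, so their folds are limited by the floor. The falls of miR-30c, miR-96 and miR-30b-5p were larger on MSC replicates 1 and 3. MSC replicate 2 lay 2.45, 1.63 and 1.68 log2 units above the mean of these 2 arrays. miR-375 was at least 3.33-fold lower.

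In total 76 of 194 miRNAs were called, 45 higher and 31 lower. miR-1224, miR-31, miR-1949 and miR-221 were 4.68-fold, 3.19-fold, 2.58-fold and 2.57-fold higher, and miR-34c and miR-34b were 3.36-fold and 2.71-fold higher. miR-183, miR-24, miR-107, miR-30e*, miR-103, miR-148b-3p and miR-342-3p fell, with log2 changes from -1.73 to -1.24. Among these, MSC replicate 2 stood furthest from the other MSC arrays for miR-24 and miR-30e*, at 1.68 and 1.05 log2 units above their mean. The fall in the miR-30 list was uneven: miR-30b-5p and miR-30c fell, also when adjusted over the list alone, while miR-30a, miR-30d, miR-30e and miR-30b-3p had log2 changes of -0.07, 0.21, -0.29 and 0.31 and did not pass (camera adjusted p = 0.31); miR-30d was -0.01 without scaling and the other 3 kept their sign under 5 scalings. The miR-30c value was -1.98, 0.66 and -1.61 on MSC replicates 1, 2 and 3 against 2.09 ± 0.01 (SD, n = 2) in untreated kidneys. On PBS replicates 1, 2 and 3 it was 0.75, 1.08 and 0.34, a log2 change from untreated of -1.37 that did not pass.

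In the injury-raised list 7 of 13 members rose and miR-24 fell (camera adjusted p = 0.072), in the miR-17 list 7 of 11 rose and miR-363 fell (camera adjusted p = 0.10), and in the miR-34 list all 3 rose (camera adjusted p = 0.10). Of the epithelial miR-200 list, miR-141, miR-200b and miR-200c rose and the other 2 of 5 did not pass (camera adjusted p = 0.10). Adjusted over the list alone, these counts were the same. Of the let-7 list, 4 of 8 rose (camera adjusted p = 0.10), and 5 rose when adjusted over the list alone; its median of 0.38 was -0.08 with quantile normalization, where let-7b and let-7c turned to -0.49 and -0.43. The groups did not overlap for 110 of the 194 tested miRNAs, where chance gives 20%. The calls that passed in 1 direction under 5 scalings were 15 higher and 17 lower, and the median change over all tested miRNAs, 0.10, was -0.05 with the percentile over all probes, -0.11 without scaling and -0.04 with spike-in scaling. The split of 45 and 31 became 22 and 34 with the percentile over all probes, 15 and 28 without scaling and 16 and 23 with spike-in scaling. With the row as a block the count was 3 (miR-375, miR-222 and miR-146b), with the row effect taken from the PBS arrays alone. Most changes of the named miRNAs stayed about as large under it, such as 2.93 ± 0.87 SE for miR-34a and -3.11 ± 1.24 SE for miR-30c. That of miR-130b went from 2.05 to 1.13. No row held both groups, so there is no value within a row. The count was 38 and 33 without untreated replicates 1 and 2, 50 without MSC replicate 3 and 122 without MSC replicate 2. It was 48 with normexp. There miR-222, miR-130b, miR-146b and miR-18a passed at 0.76, 0.71, 0.91 and 0.81, and miR-34b did not pass.

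**Figure D2:**
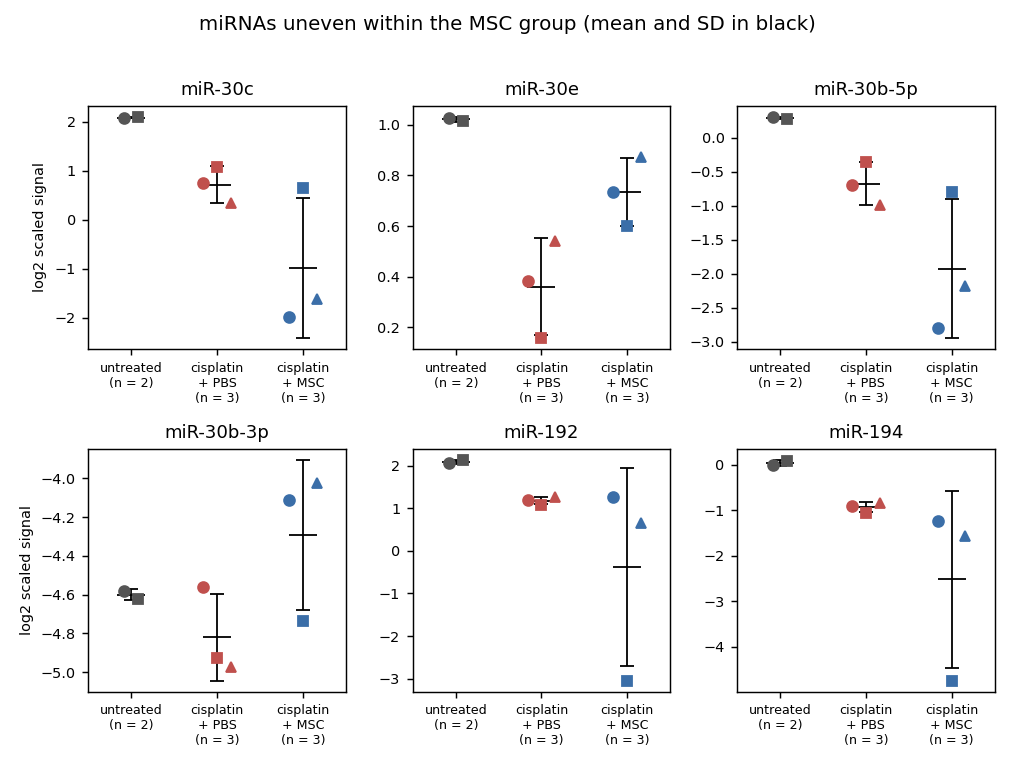
Level of 6 miRNAs on each array, drawn as log2 of the scaled signal with circles, squares and triangles for replicates 1, 2 and 3 and the group mean and SD in black. miR-30c and miR-30b-5p were lowest on MSC replicates 1 and 3 while miR-30e and miR-30b-3p were not, and miR-192 and miR-194 were lowest on MSC replicate 2, at -3.05 and -4.75.

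Whether the cells turned the cisplatin changes back was examined on the 29 miRNAs called for PBS against untreated. Of these, 12 (41.4%) lay nearer to untreated in the MSC group, where simulated MSC kidneys equal to PBS kidneys gave 60.1%, since both comparisons share the PBS arrays. miR-146b, miR-132, miR-188 and miR-378 moved back past the threshold, and miR-222 and miR-183 moved further away past it. miR-132 and miR-188 were at the floor on both untreated arrays and on MSC replicate 2, and miR-132 also on MSC replicate 3. Their return therefore depends on the floor. With normexp, which shrinks changes of dim miRNAs, their MSC minus PBS changes were 0.08 and -0.0064 and did not pass. miR-378 passed in both comparisons under only 1 of the 5 scalings, and miR-183 passed under 2 of the 5 in each comparison. Over all 194 miRNAs the slope of the MSC minus PBS change on the PBS minus untreated change was 0.08 (r = 0.10 across miRNAs, which are not independent replicates), above the simulated mean of -0.06 and its 95% range of -0.14 to 0.01. With the replicate block the slope was 0.05, where simulated noise that pairs the PBS and MSC arrays gave -0.10 to 0.02. The covariance was 0.037 against a simulated -0.032. Over the 29 called miRNAs the slope was -0.07, within the simulated -0.13 to 0.03. The slope over all miRNAs changed sign with the deposited gene-level signals, to -0.00144, with the deposited normalized table, to -0.11, and without MSC replicates 1 and 3, a setting chosen after seeing the data, to -0.15; with noise that keeps the correlation between miRNAs the simulated range was -0.33 to 0.16 and held the observed value. The slope was 0.02 and 0.03 without MSC replicates 1 and 3, 0.20 without MSC replicate 2 and 0.04 without PBS replicate 3.

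As a distance over all tested miRNAs, the root mean square log2 difference from the untreated mean was 0.697 ± 0.038 (SD, n = 3) in the PBS group and 0.988 ± 0.056 (SD, n = 3) in the MSC group. Each MSC array lay further from untreated than each PBS array, under all 5 scalings (two-sided exact permutation p = 0.10, the smallest that 3 against 3 allows). With the same-numbered arrays taken as 3 pairs, the exact permutation p = 0.25 was again the smallest possible. All MSC arrays lay in row 2 and both untreated arrays in row 1, and MSC replicates 1 and 3 had the lowest signal of all arrays. On MSC replicate 2 the distance includes miR-192 and miR-194 at -3.05 and -4.75. The distance cannot separate these features from an effect of the cells.

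The 2 cisplatin groups were also compared for shared changes from untreated. miR-34a, miR-34b, miR-34c, miR-146b, miR-21, miR-18a, miR-31 and miR-222 were among 14 miRNAs called higher in both, and miR-375, miR-499, miR-183 and miR-342-3p were among 8 called lower in both. Independent lists of these lengths would share 3.94 and 1.92, and unchanged groups simulated on the shared untreated arrays shared 0.007 and 0.008 on average. Few miRNAs pass in groups simulated without any change, so these low overlaps were set in advance. They do not test whether 2 changed groups share their changes. The changes correlated at r = 0.81 across miRNAs against a simulated 0.60, with a covariance of 0.49 against a simulated 0.049. With noise that keeps the correlation between miRNAs, the simulated range of r was -0.66 to 0.99 and held the observed value, and that of the covariance was -0.04 to 0.30 and did not. A split of the untreated arrays would leave 1 per comparison and was not made, so part of the excess may come from the shared controls. The shared calls were 22 in all, and numbered 2 and 3 without untreated replicates 1 and 2, 12, 9 and 9 without PBS replicates 1, 2 and 3, 52 without MSC replicate 2, 12 without scaling, with spike-in scaling or with normexp, and 2 with the row as a block.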

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

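The first 2 features below were looked at because they are control features that the comparisons do not use; all tests in this part were chosen after the values were seen. Of 7 control features well above background on every array, mr_1 and hur_2 were higher on all 6 cisplatin arrays than on both untreated arrays, with and without scaling. mr_1 averaged 1.79 times its untreated signal (1359 ± 54 SD, n = 2) on cisplatin arrays, with 2711 ± 226 (SD, n = 3) in the PBS group and 2147 ± 94 (SD, n = 3) in the MSC group. hur_2 averaged 1.35 times its untreated signal. Each had a two-sided exact permutation p of 0.036, the smallest that 6 arrays against 2 allow, and 0.125 after adjustment over the 7 features. The spike-in features dmr_285 and dmr_31a were at 0.973 and 0.949 times untreated. What mr_1 and hur_2 detect is not given in the sources used here. No group is large enough for a test of single outlying arrays.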

How the results depend on the processing

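Spike-in scaling, normexp, the fits within a row, the fit without MSC replicates 1 and 3 and the correlated and paired noise were chosen after seeing the data. For PBS against untreated (29 calls), the count was 16 without scaling and with spike-ins, 14 with normexp, 19 with the deposited gene-level signal, with detection on all 8 arrays and with the replicate block, 62 with only the compared groups and without MSC replicates 1 and 3, 15 with the row as a block, 44 within row 1, and 2 to 66 with single arrays left out. For MSC against PBS (51), it was 14 with the percentile over all probes, 13 without scaling, 11 with spike-ins, 23 with normexp, 30 with the deposited table, 29 with only the compared groups, 0 with the row as a block and 0 within row 2, and 7 to 115 with single arrays left out. For MSC against untreated (76), it was 43 without scaling, 39 with spike-ins, 48 with normexp, 3 with the row as a block, and 33 to 122 with single arrays left out. With the replicate block MSC against PBS gave 49 calls, 43 of them shared with the main 51 in direction, and MSC against untreated 64; the 3 called lists kept their calls. The shared calls of both cisplatin groups (22) were 12 without scaling, with spike-ins and with normexp, 2 with the row as a block, 38 without MSC replicates 1 and 3, and 2 to 52 with single arrays left out. The reversal slope of 0.08 was -0.00144 with the gene-level signal, -0.11 with the deposited table and -0.15 without MSC replicates 1 and 3; with correlated noise the slope, 0.0804, lay within the simulated range, and ran from 0.02 to 0.20 with single arrays left out. Fewer arrays, fewer miRNAs and fewer residual degrees of freedom belong to the filters, blocks and left-out arrays. The normexp offset of 50 is added to every value, so it shrinks the log2 changes of dim miRNAs by construction. Any further effect of the background correction was not tested, nor was the cause for the scalings and deposited values. Among the named risers and fallers of each comparison and the 3 called lists, 1 value reversed, miR-132 for MSC against PBS with normexp (0.0813). Of the rest, 876 kept direction and call and 281 lost the call outside the left-out arrays, with 418 and 178 for left-out arrays. Other list members and the medians of lists that were not called are outside these counts. Some of them changed sign between scalings, such as let-7c and the let-7 median. Named calls kept in all 24 settings included miR-146b and miR-21 for PBS against untreated. Dim miRNAs near the floor, such as miR-130b, miR-503 and miR-188, are limited by signal over background. The slide and the scan could not be run as blocks, since all arrays shared them.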

Other observations

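In lists too small for a set test, miR-126*, from the endothelial miR-126 hairpin, fell 1.84-fold in the PBS group and by 0.96 on the log2 scale in the MSC group against untreated, while miR-126 itself had log2 changes of 0.02 (adjusted p = 0.93) and 0.40 (adjusted p = 0.040). The muscle list's miR-499 fell in both cisplatin groups, and miR-133b had log2 changes of 0.06 and 0.04 and did not pass. The red blood cell miRNA miR-451 had log2 changes of -1.80 and -1.83 that did not pass (adjusted p = 0.33 and 0.18), with untreated arrays at -1.76 and -3.32 and MSC replicate 2 at -2.29, while it was at the floor on MSC replicates 1 and 3. The hypoxia miRNA miR-210 rose from the PBS to the MSC group, and its log2 changes from untreated, -0.66 and 0.36, did not pass (adjusted p = 0.12 and 0.26). Of the miR-132 cluster, miR-132 rose in the PBS group and miR-212 did not pass in any comparison over all miRNAs; adjusted over the list alone, both were lower in the MSC than in the PBS group. In the neuron list, miR-9 was at least 1.26-fold higher and miR-128 fell 1.42-fold in the MSC group against untreated (adjusted p = 0.020 and 0.045). Both Dlk1-Meg3 members, miR-409-3p and miR-667, did not pass in any comparison, and the liver miRNA miR-122 was not detected on any array. No member of the miR-29 list passed in any comparison, and the list of kidney miRNAs reported lost after injury had 1 of 9 members lower in the PBS group, miR-26b (camera adjusted p = 0.30). Against untreated, the MSC group had 2 of these 9 lower, miR-26b and miR-30c, and miR-200b higher, with the same counts over the list alone (median -0.72, camera adjusted p = 0.33), and against PBS only miR-200b passed, as higher, and 0 over the list alone (median -0.16, camera adjusted p = 0.79).

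Of the tests below, the midpoint share and the splits were set before their results were seen, though single miRNAs of MSC replicate 2 had been looked at, and all others were chosen after. Of these, the count of tissue markers replaced a median of markers that the floor had fixed, the count of locus partners replaced 1 of neighbour pairs and 1 of opposite arms, and the neighbours had been part of the pattern as it was noticed, the test of the slide row replaced one of whole-array labelling or scaling (the miR-30c change was -3.22 with spike-in scaling), and the simulated limit on the correlation was added once the correlation was known.

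miR-30b-5p and miR-30c fell further in the MSC group than miR-30d, miR-30e and miR-30e*, which lie beside them in the genome. Both were already lower in the PBS group than in untreated kidneys, by log2 changes of -0.96 and -1.37 that did not pass. Their PBS and untreated arrays did not overlap, and MSC replicate 2 lay within the range of the PBS arrays for both. Transcription of shared loci as the whole cause of the fall from untreated is argued against, since all 4 locus partners with room above the floor for over 50% of the fall, miR-30d, miR-30e, miR-30e* and miR-30c-2* (log2 changes 0.21, -0.29, -1.30 and 0.14, the last with a room of 2.61), fell less by over 2 SE of the within-array ratio, although ratios changed in 46 of 99 neighbour pairs. Row on the slide as the whole cause is argued against because 2 of the 4 row 2 arrays, PBS replicate 1 and MSC replicate 2, did not lie below the row 1 arrays. Selective loss during RNA preparation stays open. The main axis of spread within PBS correlated at 0.41 with the MSC minus PBS change across miRNAs. This was under the 0.95 that 95% of simulations without an effect stayed below. MSC replicates 1 and 3, where the fall was larger, had the lowest signal of all arrays. Their 75th percentiles over the spike-ins were -2.32 and -2.22 on the log2 scale against -2.02 to -1.62 on the others. An effect of the cells or of cisplatin on the stability of single miRNAs may also remain and was not tested.

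MSC replicate 2 stood apart through miR-192 and miR-194, which differed by -4.01 and -3.34 log2 units from the mean of the other MSC arrays, and 23 tested miRNAs were over 1 log2 unit lower and 13 over 1 higher, among these miR-15b, miR-30c, the stromal miR-214, miR-152 and miR-199a-3p and the leukocyte miR-150 by 2.66, 2.45, 1.53, 1.09, 1.04 and 1.29, and miR-451, which was at the floor on the other MSC arrays; the stromal miR-140 and miR-145 and the leukocyte miR-142-3p differed by -0.77, -0.33 and -0.44. RNA of muscle, liver or nervous tissue is argued against, since 0 of miR-1, miR-133a, miR-122 and miR-124 were detected on this array. Less tubule epithelium of every kind, to the extent seen for miR-192 and miR-194, is argued against by the tubule-enriched list. Its median difference was -0.20 (SD 1.79 over 12 members), with miR-30a at -0.21 and miR-10a-5p at 0.16. miR-204, miR-30b-3p and miR-30d were lower, at -1.23, -0.66 and -0.50. miR-30b-5p and miR-30c were at 1.68 and 2.45 because they were low on the other MSC arrays. A smaller loss, or less of only some kinds of tubule, was not tested. A mislabelled sample stays open, and the limit set for it in advance was met. Mislabelling was taken to leave most miRNAs called for MSC against PBS without this array off the MSC side of the midpoint. Of 115 such miRNAs, 44.3% lay on the MSC side on this array. On 74.2% of 66 miRNAs called for PBS against untreated without it, it lay on the cisplatin side. A kidney that responded differently to the cells may equally give such a profile, and the design holds no test of it.

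The real grouping of the 6 cisplatin arrays called 51 miRNAs between MSC and PBS, and the highest of the other 9 splits called 0 by limma, with 73 and at most 35 miRNAs at an unadjusted p under 0.05. The 3 other splits that also part every same-numbered PBS and MSC array called 0, with 2 to 6 at an unadjusted p under 0.05. The real one was 1 of 10 splits, too few for a share under 0.05.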
